A study of Mus musculus with 3 samples.

How the data were processed

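The series holds 10x Chromium 3′ single-cell RNA-seq of follicular T cells sorted from mouse spleen, with 2 samples labelled WT and 1 labelled Siglec-G B cell knockout (BKO). WT replicate 1 and BKO carry the label batch 1 and WT replicate 2 batch 2. The authors deposited raw UMI counts per gene and barcode for each sample and tables of Tfh and Tfr cells with UMI counts and subcluster numbers. Per the submitters' processing notes, reads were processed with Cell Ranger on mm10. Per the file headers the WT counts come from cellranger-7.0.1 and the BKO counts from Cell Ranger 4. By default the first counts reads in introns and the second does not, and whether they were counted is not given in the sources used here. The matrices deposited for WT hold called cells, and that for BKO holds 1275404 barcodes without filtering.

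Cells, their class and their subclusters were taken from the authors' tables, matched by barcode. Subclusters are the authors' shared-nearest-neighbour clusters at resolution 0.3, per the headers of the tables. The tables hold cells under 10% mitochondrial UMIs and under 4000 genes. How doublets were treated is not given in the sources used here, and no caller was run. The tables hold 10260 WT cells with 5192 distinct barcodes, since WT cells appear once per run. Suffixes of the barcodes separate the runs, and barcodes and UMI totals showed which run each stands for. The UMI totals in the table were lower than in the WT replicate 2 matrix by a median factor of 1.52, which matches thinning of that run. Of 5068 cells annotated in both runs, 527 (10.4%) were put in different classes. Each Tfr cell has a Foxp3 UMI, while 0.402%, 9.95% and 0.908% of Tfh cells have one in the matrices used here.

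The tests fixed before the data were examined assumed 2 WT libraries. Because the WT samples hold the same cells, 1 library stands against 1 and no residual degrees of freedom remain, so no count model was fitted and no p-value is given. The fixed rule of size took their place. UMI counts were summed per library and class and divided by the total and scaled as CPM. Log2 ratios compare BKO with the mean of the WT runs after adding 0.5 CPM. A gene was called higher or lower when its mean over the 3 samples was at least 20 CPM and BKO was at least 1.5 times beyond both runs. Folds carry the same 0.5 CPM.

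Genes were named by a rule set before the data were examined. Its first part needs a test and could not apply. It then takes the 10 genes ranked first per direction by the smaller of their ratios to the WT runs, leaving out TCR and immunoglobulin segments, unnamed models, ribosomal and mitochondrial genes, then members of fixed lists past the rule, the 4 members of highest CPM per list, and Siglecg, Il21, Il4, Cd40lg, Bcl6, Cxcr5, Pdcd1, Icos, Foxp3 and Cd4. Some genes that the rule takes are left out of the text and figures. The 10 genes that differ between Tfr and Tfh ratios, leading genes of subclusters and list members with values but no call were named after their values were seen. Of the classes left out, 3 of 228 unnamed models were higher and 10 lower in Tfh, and 6 and 13 of 229 in Tfr. Of 90 ribosomal genes 2 were higher and 1 lower in Tfh (median log2 ratio 0.21) and 1 and 2 in Tfr (0.13), and of 13 mitochondrial genes 0 in either. The 1 TCR segment measured in Tfh was higher, and 1 of 3 immunoglobulin genes in Tfr.

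The median log2 ratio of each of 24 fixed gene lists was placed among the medians of 10000 random lists of equal size, matched on mean CPM in 20 bins, as a description of these libraries. The lists cover Tfh identity, B cell help, TCR signalling response, inhibitory receptors, cell cycle, regulatory T cells, naive and memory cells, follicle positioning, Th1, Th2, Th17, type I interferon, heat shock and dissociation, glycolysis, oxidative phosphorylation, survival, common gamma chain cytokines, and markers of B, germinal centre B, plasma, myeloid, CD8 T and NK, erythroid and conventional T cells. A check of sex-linked genes found 0 libraries that did not match the others.

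Shares of cells carry exact Clopper-Pearson intervals and counts exact Poisson intervals, at 95%, and a count of 0 allows up to 3 counts. To compare shares across depths each cell was thinned to 2500 UMIs, and shallower cells were left out (194, 56 and 66 Tfh and 36, 2 and 9 Tfr cells of WT run 1, WT run 2 and BKO). Leading genes of subclusters are the 10 of highest fold over the other cells of the class among genes past a minimum of CPM. The minimum was set at 60, but some leading genes lie under it in their own subcluster and library, such as Snhg20 at 42.6 CPM in BKO Tfh subcluster 2.

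Gene models came from GENCODE vM21 on GRCm38 (the same assembly as mm10), where 32235 of 32285 features (99.8%) were found. Intron length is the gene's span without exons. In an added alternative a running median of the ratio over 30 bins of intron length was taken off. In simulated Tfh counts with 100 genes changed 2-fold and 100 changed 3-fold, over 6573 genes, the size rule recovered 100% of both and called 0 unchanged genes. With an intron trend simulated over 6497 genes it recovered 97% of 2-fold changes and called 126 unchanged genes, and after the adjustment 100% and 0. The same for Tfr gave 100% and 0 over 6550 genes without the trend. With it, over 6445 genes, the rule gave 91% of 2-fold changes and 92 unchanged genes, and 100% and 0 after the adjustment. These simulations held Poisson counting noise only. They had no variation between animals, sorts or libraries, so they do not measure false calls from it. The simulated trend was a smooth function of intron length, the form that the adjustment takes off. The size of this trend was not matched to the data. There, genes under 3 kb of intron had a median log2 ratio of 0.17 in Tfh and 0.18 in Tfr. The 126 and 92 unchanged genes called therefore hold for the simulated trend only and do not measure false calls from the trend in the data.

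Alternatives fixed in advance were another fold or CPM minimum, TMM scaling, thinned cells in equal numbers, library sizes without variable classes of genes, either WT run alone, cells above the fixed depth and other cycling thresholds. Others were added after the data were seen: RLE scaling of the size rule, calls of list members with TMM scaling, the intron adjustment, exclusions of cells and subclusters, classes by Foxp3 after thinning, cells over the gene ceiling, and shares outside Tfh subcluster 2. The fixed exclusion of B cells by 2 UMIs was not used, since it includes Ighm, which is in 66.0%, 75.8% and 79.7% of kept cells. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for TMM and RLE factors only.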

Results

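Siglec-G is an inhibitory receptor of B cells that binds sialic acid. The study asked how its loss in B cells bears on the T cells that help or restrain the germinal centre, the site where B cells mutate and are selected. Follicular T cells were sorted from spleens of wild-type (WT) mice and of mice with the B cell knockout (BKO) 14 days after immunisation with liposomes carrying ovalbumin. The sort took follicular helper T cells (Tfh), which help B cells, together with follicular regulatory T cells (Tfr), which express Foxp3 and restrain the response. RNA of single cells was counted with the 10x 3′ assay, which counts molecules by unique molecular identifiers (UMIs). The 3 deposited samples are WT replicate 1, WT replicate 2 and 1 BKO library.

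The matrices held 32518538 UMIs for WT replicate 1, 54059000 for WT replicate 2 and 85225125 for BKO. The authors' tables kept 5143 cells of WT replicate 1 (3727 Tfh and 1416 Tfr), 5117 of WT replicate 2 (3668 and 1449) and 8433 of BKO (6389 and 2044). Median UMIs per kept cell were 4584, 7527 and 6431. The WT samples hold the same cells: all 5554 barcodes of WT replicate 1 were among the 5721 of WT replicate 2, and UMI totals of shared barcodes correlated at r = 0.997. By chance, 13 of the 8433 BKO cells shared a barcode with WT replicate 2. The profile of a barcode in replicate 1 correlated with its own profile in replicate 2 at a median r of 0.893 over 200 barcodes, against 0.578 with another barcode. The WT samples were therefore counted as 1 library sequenced in 2 runs, and each genotype has 1 library. No test or p-value is possible, no difference has a replicate check, and genes are named by a fixed rule of size. Intervals are exact 95% intervals that cover counting error only.

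Siglecg (ENSMUSG00000030468, chromosome 7, 43408204 to 43418358, plus strand, mm10) gave 4 UMIs in WT run 1, 4 in WT run 2 and 1 in BKO over all kept cells. This equals 0.148 CPM (UMIs of the gene scaled to an equal total per library; interval 0.0403 to 0.379), 0.0920 CPM (0.0251 to 0.236) and 0.0170 CPM (0.000429 to 0.0945). The knockout is in B cells and the libraries hold T cells, so these counts check little about the labels. Residual B cells were rare: Cd79a, a part of the B cell receptor, gave 18, 36 and 35 UMIs.

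In Tfh cells the largest ratios on the lower side were those of Ccl5, Ccl4 and some transcripts of cytotoxic cells, a group named after its values were seen. Ccl5, a chemokine of effector T cells (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518, minus strand), stood at 2207 CPM in WT run 1 (interval 2186 to 2229), 2122 CPM in WT run 2 (2105 to 2138) and 32.7 CPM in BKO (31.0 to 34.4), which is 65.3-fold lower. Ccl4, a related chemokine, was 115-fold lower at 107, 102 and 0.412 CPM. Nkg7, a protein of cytotoxic granules, stood at 249, 230 and 27.6 CPM, and Eomes, a transcription factor of cytotoxic cells, at 63.6, 64.8 and 10.5 CPM. Rasgef1b (log2 ratio -4.11), Ctla2a (-3.29), Hist1h2ap (-2.44), Chst11 (-1.93) and Chsy1 (-1.86) followed on the lower side. Much of the difference lay in the subclusters led by Ccl5, Xcl1 or Eomes. Without these, log2 ratios were -1.69 in place of -6.85 for Ccl4, -3.91 in place of -6.03 for Ccl5, -1.03 in place of -3.10 for Nkg7, -1.85 for Rasgef1b, -1.52 for Ctla2a and -0.85 for Chsy1. With the cells of over 4000 genes that the authors left out, Ccl4 stood at -4.97 and Hist1h2ap at -0.74.

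The Tfh genes higher in BKO differed less. Cxcl10, an interferon-induced chemokine (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, minus strand), stood at 9.55 CPM (interval 8.21 to 11.1), 12.1 CPM (10.9 to 13.4) and 40.8 CPM (38.9 to 42.8), 3.64-fold higher in BKO. Ly6a, which encodes the interferon-inducible surface protein Sca-1 (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031, minus strand), stood at 167, 159 and 360 CPM, 2.20-fold higher. Fam43a (log2 ratio 0.99), H2-Q2 (0.93), Tubb2a (0.85), Gal (0.90), Matk (0.82), Cebpa (0.87), Gadd45b (0.75) and Cxcr4 (0.94) followed. H2-Q2, Tubb2a and Hist1h2ap have near-identical relatives with which reads can be shared, so their calls are uncertain.

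Among 6559 Tfh genes with a mean of at least 20 CPM, 26 were at least 1.5 times higher in BKO than in both WT runs and 161 were lower. The same rule with WT run 1 as the odd one gave 1 and 5 genes, and with run 2 it gave 0 and 0, which shows the noise of sequencing runs and not of libraries. Against WT run 1 alone 55 genes were higher, and 41 with library sizes without variable classes of genes. The split depends on scaling: the median gene stood at -0.10 on the log2 scale, TMM scaling moved every ratio by 0.16, and with it 63 genes were higher and 83 lower, so that 43.2% of called genes were higher in place of 13.9%. Ratios also followed intron length. Genes with over 100 kb of intron had a median log2 ratio of -0.36 and those with under 3 kb one of 0.17, and with this trend taken off 32 genes were higher and 80 lower, among them 13 and 71 of the genes above; Gadd45b, Cxcr4, Ascl2, Cxcr3, Rgs16 and Bcl2l1 no longer met the rule. The class holds subcluster 1, which carries Tfr markers, and the authors' subclusters fill it differently in WT and BKO.

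**Figure D1:**
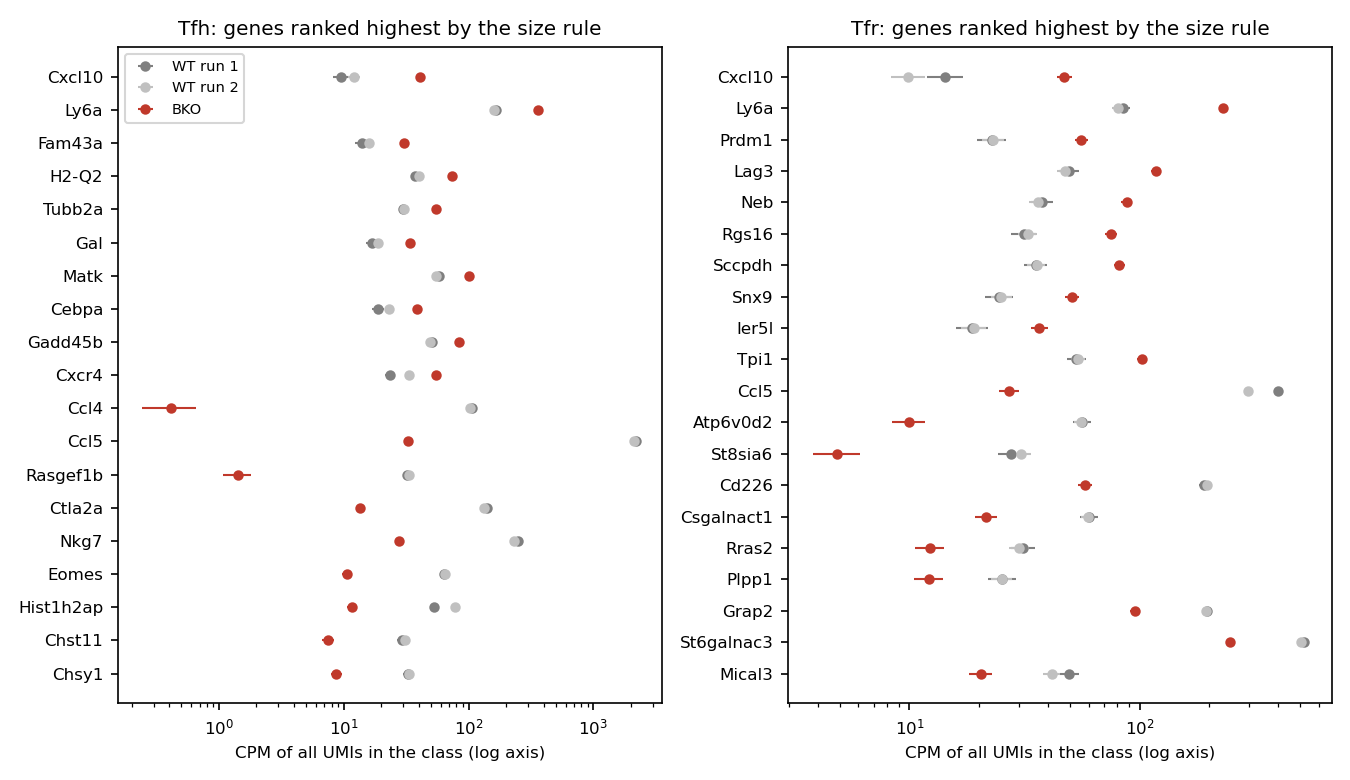
CPM (log axis) of genes among the 10 ranked first by the size rule in each direction, in Tfh (left) and Tfr (right), with WT runs in grey, BKO in red and exact 95% Poisson intervals as bars. Ccl5 in Tfh lies at 2207 and 2122 CPM in WT and at 32.7 CPM in BKO.

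Of the genes by which Tfh cells help B cells none was called in BKO Tfh cells with CPM of the total, and for Il21 this turns on scaling. Il21, the main helper cytokine, stood at 43.8 CPM (interval 40.8 to 46.9), 48.9 CPM (46.4 to 51.5) and 71.7 CPM (69.2 to 74.2), a log2 ratio of 0.62 that did not reach 1.5 times against run 2. With TMM scaling it was 0.78 and met the rule. Il4, a cytokine of antibody class switching, stood at 90.6, 98.0 and 79.1 CPM, and Cd40lg, the ligand of CD40 on B cells, at 185, 195 and 227 CPM. Log2 ratios were 0.09 for Bcl6, the factor that defines the lineage, 0.23 for Cxcr5, 0.36 for Pdcd1, 0.16 for Icos and -0.14 for Cd4. None of the 12 measured members of the B cell help list met the size rule without TMM scaling, and its median was 0.00, above 68.7% of 10000 random lists matched on expression. Of 18 Tfh identity genes, Ascl2, a factor of early Tfh cells, was higher (17.6, 15.9 and 27.2 CPM) and none was lower. The median of that list was 0.18, above 98.8% of random lists.

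After thinning each cell to 2500 UMIs, 7.25% of WT run 1 Tfh cells, 8.03% of run 2 and 12.0% of BKO cells had an Il21 UMI (intervals 6.41 to 8.15, 7.16 to 8.96 and 11.2 to 12.8). Unthinned shares were 11.0%, 15.3% and 22.3%. In Tfr cells the thinned shares were 1.67%, 1.66% and 1.77%. WT Tfr subclusters ran from 1.22 to 34.7 CPM of Il21, so the Tfr share is not background alone, and no cell type without the gene is at hand. BKO barcodes of 1 to 50 UMIs held 55.1 CPM of Il21 against 56.0 CPM in cells, and WT has none, so the part of free RNA is open. Among Tfh subclusters of at least 100 cells in each library, WT Il21 was highest in 3 (143 CPM) and 2 (67.6 CPM). Both held larger shares in BKO, with log2 ratios of Il21 of 0.06 and -0.11. The ratio was 0.78 in subcluster 0, 0.14 in 4 and 1.18 in 1, where Il21 was under 20 CPM. The Tfh values of Il21 therefore do not separate expression within cells from makeup. For Il4 the thinned Tfh shares were 16.1%, 16.6% and 13.7%, against 5.43%, 6.15% and 3.93% in Tfr cells, and the unthinned ones 22.9%, 30.2% and 23.6%. Median UMIs were 4413, 7294 and 6243 in Tfh cells and 5146, 8407 and 7055 in Tfr cells.

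In Tfh cells, 9 of the 17 lists with at least 4 measured members lay outside the central 95% of random lists, 6 above and 3 below. Because members of a list can vary together, these percentiles describe the libraries and do not measure evidence. Glycolysis genes had a median log2 ratio of 0.29, above all random lists, with Tpi1 at 0.61 and Aldoa at 0.59 and no member of 16 past the rule, or 4 with TMM scaling. All 44 oxidative phosphorylation genes had ratios above 0 (median 0.23, above all random lists, 0 past the rule). The TCR response list, genes induced through the antigen receptor, had a median of 0.19 (above 99.97% of random lists, 0 of 15 past the rule; Nfkbia 0.53, Egr2 0.27). Type I interferon genes had a median of 0.12 (99.9%, 0 of 25 past the rule), with 13 of 25 ratios above 0 and a mean of 0.026. The 4 measured genes of the germinal centre B cell list, of which Bcl6, Fas and S1pr2 are also Tfh genes, had a median of 0.28 (99.8%). None of the 4 was past the rule, or 2 with TMM scaling. The Tfh identity list is the other of the 6.

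The lists below random ones in Tfh cells were cell cycle, naive and memory like, and Th1. Of 12 cell cycle genes 3 were lower, Mki67 at 51.0, 42.7 and 19.2 CPM, Top2a (log2 ratio -1.03) and Stmn1 (-0.84), and the median was -0.29 (above 1.07% of random lists). These differences go with the ceiling on genes per cell: cells over it outside the authors' tables made up 84.6% of strongly cycling BKO cells against 59.1% and 65.2% in WT. With the cells put back, 0 of the 12 genes were lower, the median was 0.10 and Mki67, Top2a and Stmn1 stood at -0.18, -0.012 and 0.12. The cells put back count as Tfh for lack of a Foxp3 UMI alone and were not checked for T cell markers or doublets. Of 13 naive and memory genes 2 were lower, among them Satb1 (-1.01), a chromatin organiser of T cells, with a median of -0.29 (1.07%). Of 7 Th1 genes Ccl5, Ccl4 and Nkg7 were lower and Cxcr3, a chemokine receptor, was higher at 51.3, 50.2 and 82.5 CPM, with a median of -0.35 (1.10%). With random lists matched also on intron length the percentile of the TCR response list was 97.1, inside the central 95%, and that of the inhibitory receptor list was 98.0, outside it. The other 8 lists stayed outside on the same side. With the trend taken off, medians were 0.11 for oxidative phosphorylation, 0.075 for the TCR response, 0.059 for type I interferon genes and -0.19 for naive and memory genes.

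Other Tfh lists held single genes past the rule, and with TMM scaling Rgs1, Ikzf4, Bcl2l1 and Stmn1 no longer met it. Lag3 and Nfkbia did with that scaling, as did further genes counted beside their lists. Among 15 follicle positioning genes Cxcr4, Cxcr3 and Rgs16 (0.61) were higher and Rgs1 (-0.67) was lower, with a median of 0.04. Of 11 inhibitory receptor genes Entpd1, an ectoenzyme also called CD39, was lower (43.8, 41.4 and 15.7 CPM; median of the list 0.11). Entpd1 and Ikzf4 (-0.63) were the 2 lower genes of 11 regulatory T cell genes, whose median of -0.13 became 0.03 with TMM scaling. Bcl2l1 (-0.66) was lower among 15 survival genes (median 0.04), of which 2 were higher and 0 lower with TMM scaling. None of 14 heat shock and dissociation genes (median 0.10), 14 common gamma chain genes (-0.12, and 0.04 with TMM scaling) or 12 conventional T cell genes (0.07) met the rule. With TMM scaling 1 common gamma chain gene was higher. Lists with fewer than 4 measured genes have no median: Ccr4 (-1.26) was lower among 3 Th2 genes, Nkg7, Gzmk (-1.78) and Eomes were all 3 genes measured of the CD8 T and NK cell list and all were lower, and none met the rule among 1 Th17, 3 B cell, 1 plasma cell, 2 myeloid and 0 erythroid genes.

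**Figure D2:**
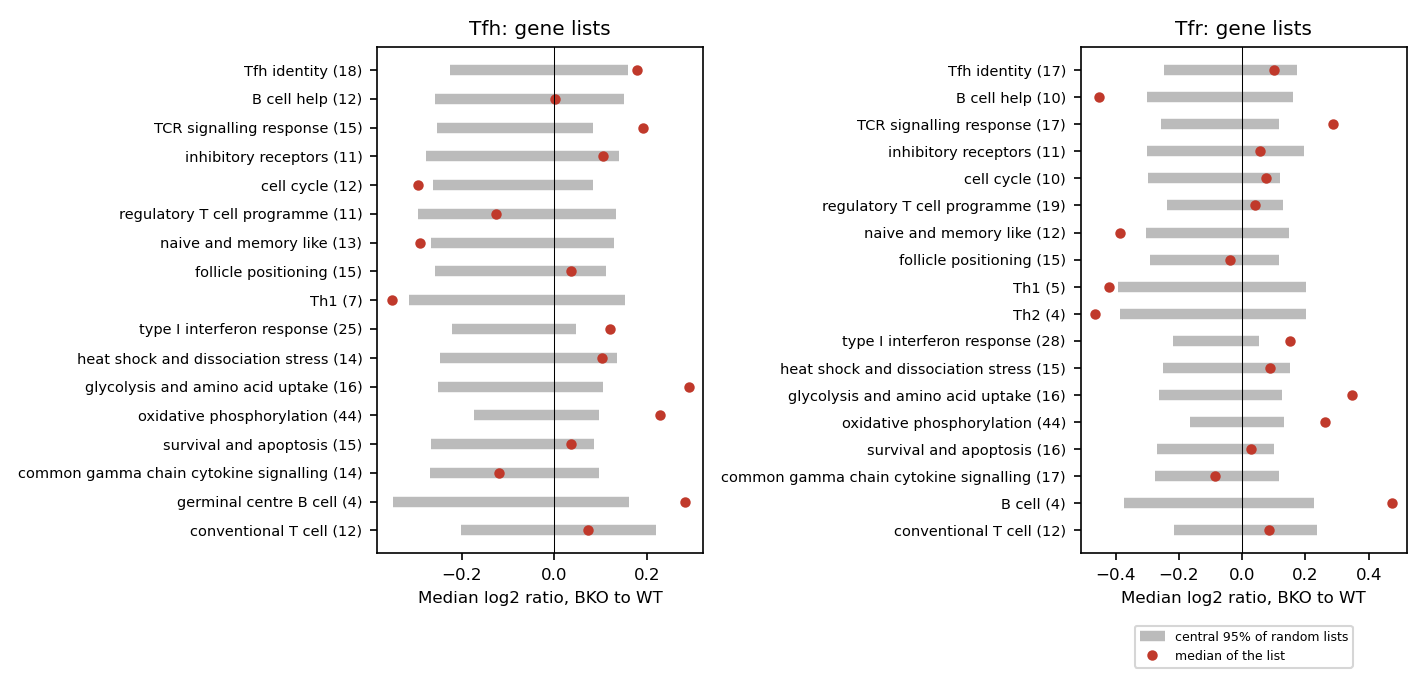
Median log2 ratio of BKO to WT (red points) of each gene list with at least 4 measured members, with their number in brackets, for Tfh (left) and Tfr (right). Grey bars span the central 95% of 10000 random lists of the same size matched on expression; glycolysis lies at 0.29 in Tfh and 0.35 in Tfr, right of the bars.

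In Tfr cells Cxcl10 and Ly6a were again the 2 genes ranked highest. Cxcl10 stood at 14.3 CPM (interval 11.9 to 17.1), 9.89 CPM (8.29 to 11.7) and 47.1 CPM (43.8 to 50.7), 3.78-fold higher in BKO, and Ly6a at 84.6, 80.6 and 231 CPM, 2.79-fold higher. Prdm1, which encodes the effector factor Blimp-1 (ENSMUSG00000038151, chromosome 10, 44437177 to 44528501, minus strand), stood at 22.9 CPM (19.7 to 26.4), 23.1 CPM (20.6 to 25.8) and 55.9 CPM (52.2 to 59.8), 2.40-fold higher. Lag3, an inhibitory receptor (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705, minus strand), stood at 49.3, 47.5 and 118 CPM, 2.42-fold higher. Neb (log2 ratio 1.24), Rgs16 (1.22), Sccpdh (1.18), Snx9 (1.02), Ier5l (0.94) and Tpi1 (0.92) completed the 10. Prdm1, Neb and Snx9, and Capg given below, were among the leading genes of BKO Tfr subcluster 1. That subcluster held a larger share of Tfr cells in BKO, so these ratios do not separate expression within cells from makeup.

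On the lower side of Tfr cells, Ccl5 stood at 400 CPM (interval 387 to 414), 295 CPM (286 to 305) and 27.1 CPM (24.6 to 29.8), 12.6-fold lower in BKO, with a log2 ratio of -0.89 in place of -3.66 without Tfr subcluster 6. Cd226, an activating receptor that shares its ligands with Tigit (ENSMUSG00000034028, chromosome 18, 89176967 to 89272229, plus strand), stood at 190, 196 and 57.9 CPM, 3.32-fold lower. Atp6v0d2 (log2 ratio -2.43), St8sia6 (-2.47), Csgalnact1 (-1.45), Rras2 (-1.28), Plpp1 (-1.03), Grap2 (-1.03), St6galnac3 (-1.04) and Mical3 (-1.14) followed. Foxp3, which defines the class since each Tfr cell has a UMI of it, stood at 356, 331 and 349 CPM.

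Among 6539 Tfr genes, 58 were higher and 157 lower in BKO by the size rule, against 0 and 3 with WT run 1 and 0 and 1 with WT run 2 as the odd one. Against WT run 1 alone 92 were higher. The median gene stood at -0.09, TMM scaling moved ratios by 0.11, and with it 104 genes were higher and 74 lower, 58.4% of called genes in place of 27.0%. The trend over intron length was like that in Tfh cells (median -0.36 over 100 kb and 0.18 under 3 kb). With it taken off 74 genes were higher and 44 lower, among them 41 and 35 of the genes above; Nfkbia, Nrp1, Bach2, Cxcr4, Itgb1, Aldoa, Bcl2, Il6ra and Ighm no longer met the rule.

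Inhibitory receptors and effector genes of regulatory T cells stood out singly in Tfr cells rather than as lists. Of 11 inhibitory receptor genes 3 were higher: Lag3, Tigit (44.2, 48.9 and 77.1 CPM) and Ctla4, which removes costimulatory ligands (357, 355 and 615 CPM). Of 19 regulatory T cell genes Prdm1, Lag3, Ctla4 and Capg (211, 184 and 317 CPM) were higher, and Lrrc32 (log2 ratio -0.65), the surface anchor of latent TGF-beta, and Nrp1 (-0.74) were lower, Lrrc32 not with TMM scaling. With TMM scaling 3 inhibitory receptor genes were higher, and 5 regulatory T cell genes were higher and 1 lower. The medians of these lists were 0.06 and 0.04, above 76.8% and 81.8% of random lists. With the intron trend taken off they were 0.32 and 0.27, and inside the central 95% of random lists matched also on intron length.

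Of the 18 Tfr lists with at least 4 measured genes, 9 lay outside the central 95% of random lists, 5 above and 4 below, and all 9 stayed outside on the same side with lists matched also on intron length. Glycolysis genes had a median of 0.35, above all random lists, with Tpi1 (53.2, 54.1 and 102 CPM) and Aldoa (0.73) the 2 of 16 past the rule. Oxidative phosphorylation genes had a median of 0.26 (above all random lists, 43 of 44 ratios above 0, 0 past the rule). The TCR response list had a median of 0.29 (above all random lists), with Nfkbia (0.72) higher, 1 of 17, and with Nr4a3 at -0.64. Type I interferon genes had a median of 0.15 (99.98%), with Igtp (0.73) higher and Ifi208 (-0.76), which has close copies, lower among 28, Ifi208 not with TMM scaling. The B cell list rested on 4 genes, Ighm, Ighd, Igkc and Cd74, with Ighm higher (639, 663 and 1020 CPM) and a median of 0.47 (99.99%). With TMM scaling 3 glycolysis, 2 TCR response, 3 type I interferon and 2 B cell list genes were higher and 0 of these lists lower. With the trend taken off, medians were 0.15 for oxidative phosphorylation and 0.19 for the TCR response.

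The B cell help list was below all random lists in Tfr cells (median -0.45), with Tnfsf11, the cytokine RANKL, lower at 147, 159 and 79.8 CPM, 1 of 10, and Il4 at 29.1, 28.9 and 21.2 CPM. Of 12 naive and memory genes 2 were lower, among them Bach2 (-0.84), a repressor of effector genes (median -0.39, above 0.150% of random lists). Of 5 Th1 genes Ccl5 and Nkg7 (-1.30) were lower and Cxcr3 was higher at 31.8, 30.6 and 58.9 CPM (median -0.42, 1.40%; -0.27 with the intron trend taken off). The 4 Th2 genes had a median of -0.46 (0.380%) and none met the rule. Log2 ratios of Tfr genes named in advance were 0.14 for Il21, -0.23 for Cd40lg, -0.16 for Bcl6, 0.10 for Cxcr5, 0.34 for Pdcd1, 0.47 for Icos and -0.25 for Cd4.

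Among the remaining Tfr lists, Cxcr4 (0.92), Cxcr3 and Rgs16 were higher and Ccr6 (-0.88) and Itgb1 (-0.72) lower among 15 follicle positioning genes, whose median of -0.04 became 0.08 with TMM scaling. Bcl2 (-0.80), which protects from cell death, was the lower gene of 16 survival genes (median 0.03) and with Il6ra (-0.62) of 17 common gamma chain genes (-0.09, and 0.03 with TMM scaling, with which Il6ra did not meet the rule). None of 17 Tfh identity genes (median 0.10), 10 cell cycle genes (0.08), 15 heat shock genes (0.09) or 12 conventional T cell genes (0.09) met the rule. With TMM scaling 1 gene each of the Tfh identity, heat shock, survival, common gamma chain and myeloid lists was higher. The cell cycle median was 0.33 with the cells over the gene ceiling. With the intron trend taken off, medians had the other sign for cell cycle (-0.082), heat shock (-0.029) and follicle positioning genes (0.065). Lists without a median were Th17 (Ccr6 lower of 2), plasma cell (Prdm1 higher of 2, also a regulatory T cell gene), CD8 T and NK cell (Nkg7 lower, 1 measured), germinal centre B cell and myeloid (0 of 2 each past the rule) and erythroid (0 measured).

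The differences of Tfh and Tfr cells ran largely in parallel. Over 6310 genes measured in both, log2 ratios correlated at r = 0.81 across genes, which are not independent replicates, and at 0.70 with the intron trend taken off. Of 19 genes higher in Tfh and 46 in Tfr cells, 16 were higher in both, against 0.139 for independent lists. Of 137 lower genes in each class, 49 were lower in both, against 2.97, and no gene went opposite ways past the rule. With the intron trend taken off, 19 of 25 and 60 higher genes and 14 of 61 and 32 lower genes were shared. Both classes come from the same libraries, so any difference between libraries counts in both. In 10 genes the ratios differed by at least 1 on the log2 scale, in each case with the Tfr ratio above the Tfh ratio: Ccl5, Nkg7, Entpd1 (-1.41 in Tfh and 0.06 in Tfr), Runx3 (-1.66 and 0.01), Ifngr1 (-0.60 and 0.76), Serpina3g (-0.37 and 0.91), Ppp3ca, Hip1, Dscam and Smad7. The difference itself was not tested. Ccl5 and Nkg7 were leading genes of WT Tfh subcluster 5, which was nearly absent from BKO. It held a larger share of WT Tfh cells than the subcluster led by Ccl5 held of WT Tfr cells. The 10 genes therefore do not separate a response that differs between the classes from makeup.

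Tfr cells made up 27.5% of follicular T cells in WT run 1 (exact binomial interval 26.3 to 28.8), 28.3% in run 2 (27.1 to 29.6) and 24.2% in BKO (23.3 to 25.2). By a Foxp3 UMI after thinning the shares were 19.4%, 19.3% and 14.8%. Both cell types were sorted together, and the gates can set this share. Detection of Foxp3 bears on it too, since each Tfr cell has a UMI of it and 10.4% of WT cells annotated in both runs changed class between them. Tfh subcluster 1, which carries Tfr markers, counts as Tfh with 927, 867 and 917 cells, so the share is not that of all cells with a Tfr profile.

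The authors' subclusters of both classes were filled differently in BKO. Tfh subcluster 5, led by Ccl5, Ccl4 and Ccl3 in WT, held 9.63% and 9.90% of Tfh cells in the WT runs and 11 cells, 0.172% (interval 0.0860 to 0.308), in BKO. Without use of clusters, 9.60%, 9.99% and 0.253% of thinned Tfh cells had at least 5 Ccl5 UMIs. Tfh subcluster 6, led by Xcl1 and Eomes, held 4.86%, 4.83% and 1.42%. Tfr subcluster 6, also led by Ccl5 and Ccl4, held 1.91% and 1.38% of WT Tfr cells and 0 of 2044 in BKO, which allows a share of up to 0.147%.

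Tfr subcluster 1, led by Neb, Prdm1, S100a4 and S100a6 in each library, held 16.2%, 17.1% and 36.3% of Tfr cells (BKO interval 34.2 to 38.4). Tfr subcluster 0, led by Lmo4 and St8sia1 among others, held 39.1%, 39.96% and 15.4%. For Tfh subcluster 2, 0 of the 10 leading genes in BKO were leading genes in WT run 2 (Rflnb, Tesc and H2-Q2 led it in BKO, Mif, C1qbp and Npm1 in WT), so its shares of 6.90%, 7.33% and 34.1% are not read as a difference in makeup. Tfr subcluster 2 shared 2 of 10 leading genes between BKO and WT run 1 and 4 with run 2, and its shares of 19.4%, 17.7% and 22.0% are not read so either. In the others BKO shared 4 to 8 of 10 with either run. The interferon-stimulated-like subclusters, led by Ifit1 and Ifit3 (in Tfr read from BKO only, since WT cells were few), held 1.503%, 1.55% and 2.10% of Tfh (subcluster 7) and 0.777%, 0.828% and 1.57% of Tfr cells (subcluster 5).

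The share of Tfh subcluster 2 bears on all others of the class. Subcluster 0 held 27.8%, 28.6% and 18.9%, and 1, which carries Tfr markers such as Il2ra and Ikzf4, held 24.9%, 23.6% and 14.4%. Of the Tfh cells outside subcluster 2 these were 29.9%, 30.9% and 28.7%, where the BKO interval overlaps those of both WT runs, and 26.7%, 25.5% and 21.8%. Subcluster 3, led by Sostdc1 and Egr3, held 16.5%, 16.6% and 20.5% (17.8%, 17.9% and 31.1% outside subcluster 2), the naive or memory-like subcluster 4, led by Klf2 and S1pr1, 6.20%, 6.11% and 7.72% (6.66%, 6.59% and 11.7%), and the cycling-like subcluster 8 1.72%, 1.44% and 0.720% (1.84%, 1.56% and 1.09%). The cycling cells that the gene ceiling took out, more of them in BKO, are in no subcluster, so the shares of subcluster 8 are not read as a difference. Of the other Tfr subclusters, 3, led by Nr4a3 and Egr3, held 15.04%, 16.01% and 19.0%, and 4, led by Penk, held 7.56%, 6.97% and 5.82%.

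**Figure D3:**
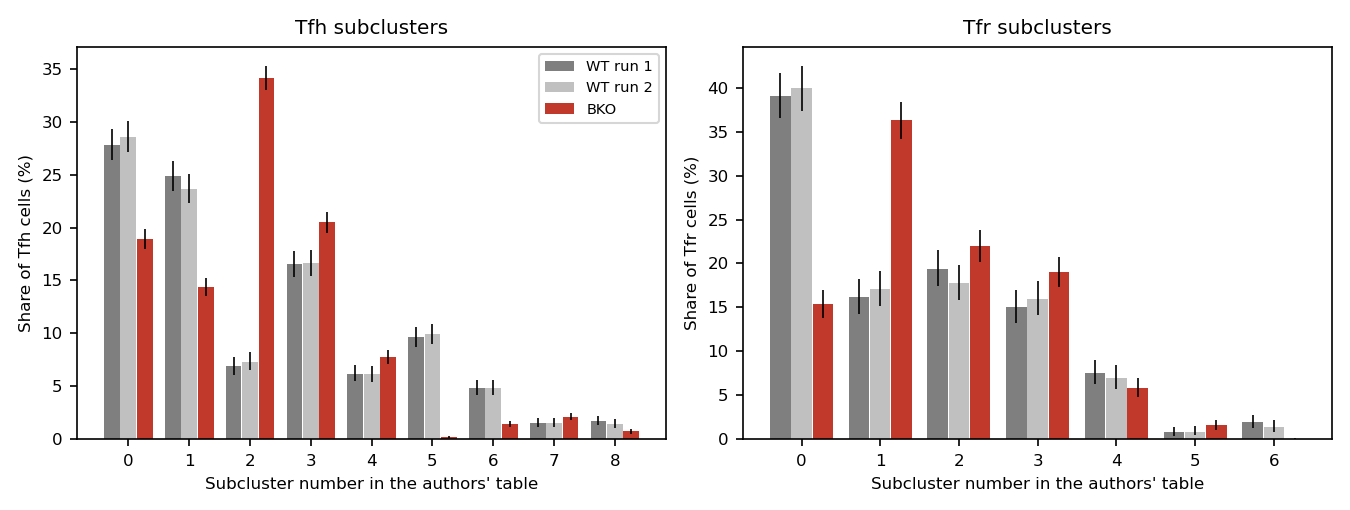
Share of Tfh cells (left) and Tfr cells (right) in each of the authors' subclusters, in percent, for the WT runs (grey) and BKO (red), with exact 95% binomial intervals as bars. Tfh subcluster 5 stands at 9.63% and 9.90% in WT and 0.172% in BKO, and Tfr subcluster 1 at 16.2%, 17.1% and 36.3%.

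Ly6a was higher in BKO within most subclusters. By the size rule it was higher in 4 of the 5 Tfh subclusters with at least 100 cells in each library (log2 ratios 0.46 to 1.77; 3 of 5 with the intron trend taken off) and in 5 of 5 Tfr subclusters (0.90 to 1.59), with subcluster 2, whose leading genes differ, among them in each class. In Tfr cells Lag3 was higher in 4 of 5 subclusters (3 with the trend taken off), and Cxcr3 and Rgs16 in 3 of the 4 in which they reach 20 CPM. Here and below a gene reaches 20 CPM by its mean over the 3 samples, as in the size rule. Prdm1 reaches 20 CPM in 1 Tfr subcluster, number 1, with a log2 ratio of 0.52 against 1.26 over all Tfr cells. It is past the rule there only with the trend taken off (0.80). Neb reaches 20 CPM in Tfr subclusters 1 and 4. Its log2 ratio was 0.42 in subcluster 1, past the rule only with the trend taken off (0.78), and 1.38 in subcluster 4, past the rule. Il21 was higher in 1 of the 4 Tfh subclusters in which it reaches 20 CPM, and Ccl5 was lower in 3 of 4 Tfh and 4 of 5 Tfr subclusters. WT held 35.1 to 48.9 CPM of Ccl5 in these Tfh subclusters and 34.7 to 80.9 CPM in these Tfr subclusters, against 2207 and 2122 CPM over all Tfh cells, so free RNA from the cells of high Ccl5 can give these calls. Among these subclusters of at least 100 cells, Cxcl10 was higher in 1 of the 2 Tfh subclusters and in the 1 Tfr subcluster in which it reaches 20 CPM. Ctla4 was higher in 2 of 5 Tfr subclusters. The interferon-stimulated-like subclusters had too few cells for this comparison. There Cxcl10 stood at 135 CPM in WT run 1 and 611 CPM in BKO (Tfh subcluster 7) and at 961 CPM in BKO (Tfr subcluster 5). In Tfh cells Lag3 was higher in 1 of 4, Rgs16 in 1 of 3 and Cxcr3 in 2 of 5. Over all genes, 15 to 48 were higher and 33 to 266 lower per Tfh subcluster, and 40 to 187 higher and 79 to 508 lower per Tfr subcluster, where fewer cells give noisier values.

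Ly6a and Cxcl10 were also counted in more BKO cells. After thinning, 22.4% and 22.0% of WT and 42.1% of BKO Tfh cells had a Ly6a UMI, and 10.7%, 11.4% and 26.9% of Tfr cells. Unthinned shares were 30.5%, 36.6% and 58.3% in Tfh and 18.4%, 22.8% and 40.2% in Tfr cells. A Cxcl10 UMI was found in 1.27%, 1.69% and 3.75% of thinned Tfh and 1.52%, 1.73% and 5.45% of thinned Tfr cells, and unthinned in 2.25%, 2.81% and 6.12% of Tfh and 2.68%, 4.14% and 9.44% of Tfr cells. No cell type without these genes is at hand to give a background share. In BKO barcodes of 1 to 50 UMIs, Ly6a stood at 326 CPM and Cxcl10 at 46.2 CPM, against 327 and 42.5 CPM in cells, and WT has no such barcodes, so the part of free RNA in these shares is open.

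Cycling cells, with at least 2 UMIs of 13 G2/M genes after thinning, made up 2.93% of kept cells in WT run 1 (interval 2.48 to 3.44), 2.53% in run 2 (2.12 to 3.001) and 1.73% in BKO (1.47 to 2.04). Unthinned shares, which follow depth, were 7.39%, 12.8% and 7.99%. In Tfh cells the thinned shares were 3.28%, 2.93% and 1.71%, and in Tfr cells 2.03%, 1.52% and 1.82%, whose intervals overlap. The authors kept cells of under 4000 genes. In the matrices used here, 295, 375 and 821 cells outside their tables lay over this ceiling, of which about the same share was cycling. The authors' counts of WT run 2 were lower than those used here, so for that run the ceiling acted on other gene numbers. With these cells put back, unchecked for T cell markers or doublets, the shares were 4.65%, 4.601% and 4.28%.

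**Figure D4:**
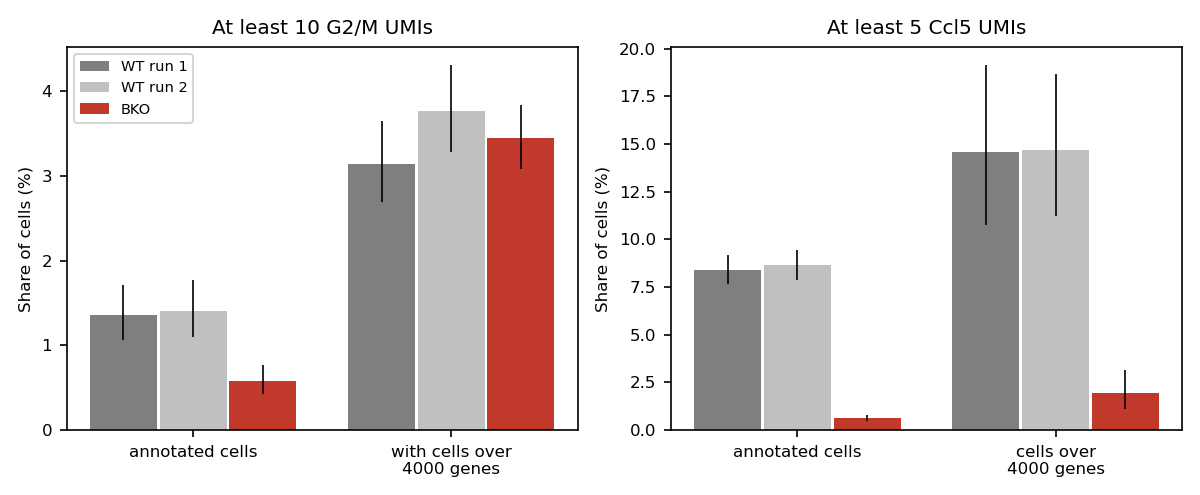
Left, share of cells with at least 10 UMIs of G2/M genes, in percent, among annotated cells and with the cells over 4000 genes put back; right, share with at least 5 Ccl5 UMIs among annotated cells and among cells over 4000 genes. Bars are exact 95% binomial intervals; the BKO share of cycling cells is 0.581% among annotated cells and 3.45% with the cells put back.

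**Figure D5:**
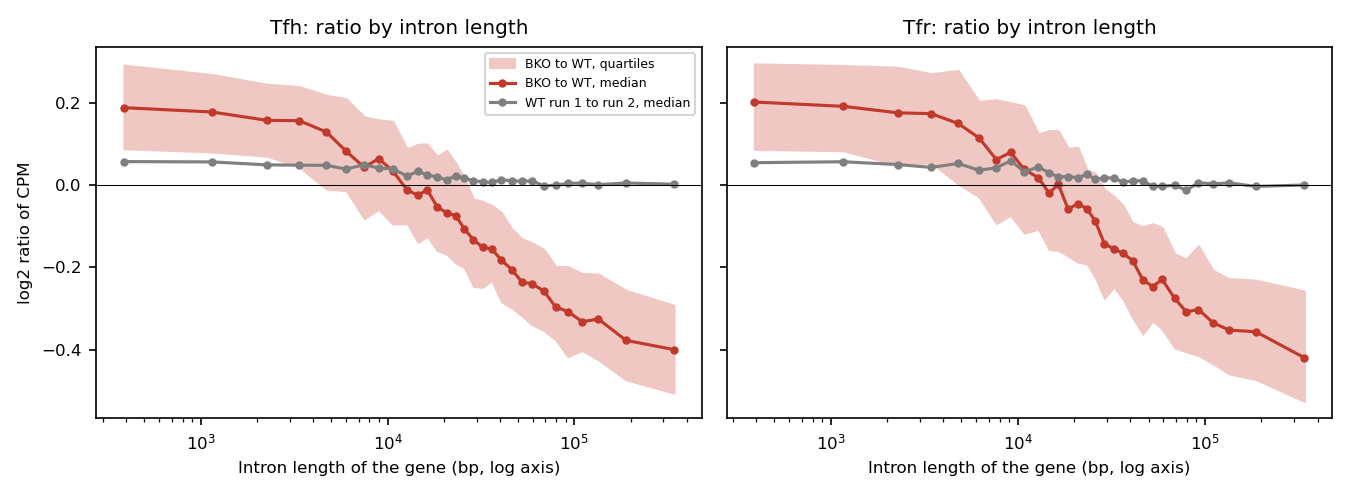
Median log2 ratio of CPM of BKO to WT (red, quartiles shaded) and of WT run 1 to run 2 (grey) over 30 groups of genes ordered by intron length in bp (log axis), for Tfh (left) and Tfr (right). The red line lies at a median of 0.17 under 3 kb and of -0.36 over 100 kb in Tfh.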

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

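All tests of explanations in this part, and their bounds, were chosen after the results were seen.

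Cells that the authors left out for more than 4000 genes were flagged because they carry a strong cycling signal outside the main measurement. At least 10 UMIs of G2/M genes were found in 34.2% of the 295 such cells of WT run 1 (interval 28.8 to 39.96), in 36% of the 375 of WT run 2 (31.1 to 41.1) and in 32.9% of the 821 of BKO (29.7 to 36.2), against 1.36%, 1.41% and 0.581% of kept cells. The cells over the ceiling made up 59.1%, 65.2% and 84.6% of all cells so defined. Genes were counted in the matrices used here, and the authors' counts of WT run 2 were lower, so for that run the cells may not be those that their ceiling took out. The lower share of cycling cells among kept BKO cells (-0.996 percentage points) became -0.342 points with these cells put back, with intervals that overlap both WT runs. The ceiling may therefore account for most of it, if these cells are T cells, for which they were not checked. A difference due to genotype stays untested.

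Barcodes of 1 to 50 UMIs in the unfiltered BKO matrix (907649 barcodes with 1686503 UMIs) were flagged because they hold signals above the level in BKO cells. The G2/M genes together stood at 367 CPM (interval 339 to 397) there and at 89.3 CPM in cells, a 4.11-fold difference. Cells here are the kept ones, without the 84.6% of strongly cycling BKO cells that the gene ceiling took out, which lowers the level in cells. Lars2 stood at 4403 CPM against 782 CPM in cells. Ccl5 stood at 39.1 CPM against 31.2 CPM, and Ly6a at 326 CPM against 327 CPM.

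The near absence of cells with high Ccl5 from BKO was weighed against 3 explanations. The gene ceiling is argued against, since 1.95% of BKO cells above it had at least 5 Ccl5 UMIs (interval 1.12 to 3.15), against 14.6% (10.8 to 19.1) and 14.7% (11.2 to 18.7) in the WT runs. A single expanded WT clone is argued against, since the most frequent V segment of Tfh subcluster 5 in WT run 2, Trbv2, was seen in 8.54% of its cells (interval 5.88 to 11.9) and in 9.05% of the other Tfh cells. A difference between animals or sorts and an effect of the genotype cannot be told apart, because the gap of -9.59 percentage points rests on 1 library each.

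The lower ratios of genes with long introns were weighed against 3 explanations. Counting introns in WT alone would take most UMIs from genes read mainly in introns, but 1.64% of the 855 Tfh genes with over 100 kb of intron had a log2 ratio below -1 (quartiles -0.45 to -0.24) and the 10 most abundant of them ran from -0.56 (Inpp4b) to 0.18 (Camk1d), 9 of them below 0. Makeup of the subclusters is argued against as the whole cause, since the gap between long and short introns within Tfh subclusters ran from -0.18 to -0.48. With BKO subclusters weighted as in WT, 64.7% of the Tfh gap was left. This weighting takes subcluster 2 as the same cells in WT and BKO, though its leading genes differed, so the 64.7% does not fully take makeup out. A difference in library preparation, RNA handling or read processing and an effect of the genotype cannot be told apart: the gap between the WT runs was -0.0463, but these share 1 library.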

How the results depend on the processing

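Added after the data were seen were RLE scaling of the size rule, the intron adjustment, exclusions of cells, Foxp3 classes, the gene ceiling, shares outside Tfh subcluster 2 and the WT runs alone for gene lists and for Tfr against Tfh. No paired analysis was possible because WT and BKO share only replicate number 1 and no test was run. Planned and not run, since each needs 2 WT libraries, were the edgeR, DESeq2 and limma fits with their filters, the interaction test, camera, fry and the estimated correlation. RLE on gene lists moves each gene alike and was not run either.

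The 26 higher and 161 lower Tfh genes became 2 and 41 at 2-fold, 13 and 75 at 50 CPM, 63 and 83 with TMM scaling and 58 and 86 with RLE scaling. The higher count was 41 with library sizes without variable classes of genes, and 31 to 55 against either WT run alone, and the lower count was 80 after the intron adjustment. The 58 higher and 157 lower Tfr genes became 8 and 14 at 2-fold, 33 and 90 at 50 CPM, 104 and 74 with TMM and 102 and 75 with RLE scaling. The higher count was 74 to 92 against either run alone, and the lower count was 44 after the intron adjustment. Fewer genes pass a stricter minimum by construction, and for the others the cause was not tested. Other settings stayed within 1.5 times, among them thinned cells (25 and 180 in Tfh, 52 and 208 in Tfr). The 10 genes that differ between Tfr and Tfh became 337 with no minimum of expression, where counts of few UMIs enter. The 9 lists outside random ones became 8 in Tfh and 7 in Tfr with thinned cells.

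For 28 named genes per class under 10 settings each, moves were set against the counting intervals of BKO and WT run 1. In Tfh 219 of 280 values and in Tfr 250 of 280 moved less than these allow, and 61 and 30 moved more. Of the genes past the rule 0 changed direction, and changes of direction in the other genes were not counted. The lower Tfr share held in each setting (-3.69 percentage points, lowest -4.57). Gaps of subcluster shares kept their direction throughout. Against either run alone, that of Tfh subcluster 5 ran from -9.72 to -9.46 and that of Tfr subcluster 6 from -1.91 to -1.38, more than the narrow BKO intervals. Of the Tfh cells outside subcluster 2, the gaps of subclusters 0, 1, 3, 4, 5, 6, 7 and 8 were -1.66, -4.32, 13.3, 5.09, -10.3, -3.05, 1.54 and -0.609, in place of -9.29, -9.90, 3.92, 1.56, -9.59, -3.42, 0.569 and -0.861, since subcluster 2 holds more of the BKO cells.

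The gap in cycling cells (-0.996 points) was -2.08 unthinned, -1.93 at 1 UMI, -0.678 at 3 UMIs, -0.342 with the cells over the gene ceiling and -0.00967 at 10 UMIs with those cells. The cell cycle list with those cells had a median of 0.10 in Tfh in place of -0.29 and of 0.33 in Tfr in place of 0.08. In Tfh cells (-1.40) it was -2.04 unthinned, -2.21 at 1 UMI and -0.917 at 3 UMIs. In Tfr cells (0.0435) the sign is open: -1.89 unthinned, -1.04 at 1 UMI, -0.161 at 3 UMIs, and -0.211 to 0.298 against either run alone. Unthinned shares follow depth, and for the other settings the cause was not tested. Depth limits rare transcripts most: Siglecg rests on 1 to 4 UMIs per sample.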

Other observations

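Nothing in this part was planned; its values were picked after they were seen.

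The genes in which Tfr ratios lay furthest above Tfh ratios included Runx3, a factor of cytotoxic T cells, and Ifngr1, a chain of the interferon gamma receptor. Smad7, an inhibitor of TGF-beta signalling, had a log2 ratio of -0.75 in Tfh and 0.26 in Tfr cells, and Ppp3ca, a catalytic subunit of calcineurin, -1.51 and -0.18. Dscam stood at -1.47 and -0.41, and Hip1 at -1.47 and -0.19. These ratios do not separate expression within cells from makeup of the classes.

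V segments of the T cell receptor were uneven in some subclusters. In BKO Tfr subcluster 1, Trav13-4-dv7 was seen in 66 of 742 cells (8.89%, interval 6.95 to 11.2) and in 38 of the other 1302 Tfr cells (2.92%), and Trav9-4 in 58 cells (7.82%) against 34 (2.61%). This was not particular to that subcluster. In the 119 cells of BKO Tfr subcluster 4 the segments were seen in 8.40% (rest 4.88%) and 6.72% (rest 4.36%). Trav9-4 was seen in 4.91% of BKO Tfh subcluster 1 and in 1.77% of the other Tfh cells. In Tfr subcluster 1 of WT run 2 the most frequent segment was Trbv2, in 7.26% of cells against 7.91% of the rest. Neither Trav13-4-dv7 nor Trav9-4 was among the 3 most frequent there. In Tfh subcluster 0 of BKO, Trbv2 was seen in 18.0% of cells (15.8 to 20.2) and in 10.5% of the other Tfh cells. In WT run 2 the same subcluster had Trbv2 in 11.2% (9.31 to 13.2) and the rest in 8.13%. The 3′ assay reads V segments in part of the cells, 465 of the 742 in the first case.

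Ighm, the immunoglobulin mu gene, was counted in most of these T cells, at 461, 477 and 587 CPM, while Cd79a stood at 0.666, 0.828 and 0.593 CPM.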
